A study of Mus musculus with 2 samples.

How the data were processed

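Single-cell RNA of mouse retina was measured in 2 libraries, 1 from mice given PBS and 1 from mice given the treatment that the labels call MSC-sEV, both 2 weeks after optic nerve injury. Per the labels' protocols, each library came from the pooled retinas of 6 C57BL/6 mice aged 6 to 8 weeks, digested in 15 U/mL papain and 0.1 mg/mL DNase at 34 °C for 15 min. CD45, the surface marker of leukocytes, was then used to enrich cells on magnetic beads. Libraries were made with a droplet kit for 3′ ends and sequenced on an Illumina instrument, per the labels' protocols. The deposited values were UMI counts per gene and cell barcode, which the authors made with Cell Ranger 3.0.2 against mm10, per the labels' protocols and the submitters' processing notes. A UMI is a tag that marks 1 captured RNA molecule, so PCR copies were counted once. The annotation release behind the counts was not given in the sources used here. Of the 31053 genes, 30934 were found by gene ID in GENCODE M21 for GRCm38, the same build as mm10, and coordinates were taken from it.

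The PBS library held 1676 barcodes and 8439740 UMIs, and the MSC-sEV library 2593 barcodes and 16987131 UMIs. Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial counts were kept, which left 1347 and 2323. Scrublet, run per library at an expected rate of 2%, called 3 and 6 of these as doublets (0.223% and 0.258%), and the remaining 1344 and 2317 cells were analysed. So few calls leave doublets open, and a setting without the 2% of cells with the highest scores was added. Both libraries were clustered together on 2000 variable genes, with mitochondrial, ribosomal protein and sex-linked genes left out, 30 principal components and 20 nearest neighbours, by the Leiden method at resolution 1.0. This gave 16 clusters. A cluster was named "-like" from 28 lists of cell type markers when at least 3 markers of a class were seen in at least 20% of its cells and at least 2-fold above the other cells. It stayed unnamed when markers of another class were more frequent among its top 10 genes, or when it was shallow without an own marker there.

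Each group had 1 library, so no test between mice was possible and no p-values were computed. Shares of cells are given with exact Clopper-Pearson intervals and sums of UMIs with exact Poisson intervals. Levels are given as CPM, the UMIs of a gene scaled to the same total of UMIs in each class and library, and their ratios have exact conditional binomial intervals. These are 95% intervals and cover counting error only, not the spread between mice or between cells. Where a library had 0 counts, a floor of 3 counts over the class was used, and such genes entered list medians at that bound. A fold given as "at least" rests on this floor and leaves out counting error. The lower bound of its exact interval lies below it. For 21 gene lists, the median log2 ratio over members with at least 20 counts was set beside 10000 random lists of the same size, matched on level in 20 bins, as a description of these libraries. A list median has a 95% interval from its ranked members, or their range in short lists. This shows the spread between genes and not counting error. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs.

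The classes, markers, gene lists, settings and named-gene rule were chosen before the data were examined. Named genes were the 10 highest and 10 lowest by the bound of the ratio interval nearest to 1. They had at least 50 counts and a UMI in at least 10% of cells of the library with the higher level. Mitochondrial, ribosomal protein, sex-linked and model genes and markers of other classes were left out. For a described gene list, the 2 to 4 members with the most counts and the 2 with the largest ratio in the direction of the median could be named as well. Some genes that met these rules are not reported here. The rule was applied to microglia-like, rod-like and Müller glia-like cells. It could not be applied to monocyte or macrophage-like cells, because the PBS library had 0 of them. These cells were reclustered by the same steps, so the markers of a subcluster were compared with the other monocyte or macrophage-like cells only.

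Ratios were tested on counts simulated as Poisson draws from class totals, with 200 changed genes per class. Spread between cells was not simulated. Coverage near 95% was thus built into the draws and does not show that the intervals are wide enough for real cells. The interval held the true ratio for 96.7% of 10470 genes in microglia-like, 96.2% of 8545 in rod-like and 96.1% of 10202 in Müller glia-like cells. Genes set to a 2-fold change were recovered in 65.3%, 79.8% and 80.8% of cases, and genes set to a 4-fold change in 89.5%, 94.6% and 100%. Alternatives planned in advance changed the cell filter, the doublet treatment, the resolution, the variable genes, the class of each cell, the denominator, the scaling, the weight of cells, the depth and the count minimum. Further alternatives were added after seeing the data. They left out more doublets, took each microglia-like cluster alone, kept genes at least 3 times above rod-like cells, or left out Müller glia-like cells with UMIs of at least 3 microglia markers. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.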

Results

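The libraries address which immune cells are present in the injured retina with and without MSC-sEV, and the series title names a monocyte subset. The 1344 analysed PBS cells had a median of 2596 UMIs and 5.08% mitochondrial counts. The 2317 analysed MSC-sEV cells had a median of 2922 UMIs and 2.59% mitochondrial counts. Each group was 1 pool of mice, so none of the differences has a replicate check.

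Leukocytes other than microglia were found only in the MSC-sEV library among the named clusters. Monocyte or macrophage-like cells made up 201 of its 2317 cells (8.68%, 7.56 to 9.90), T cell-like cells 57 (2.46%, 1.87 to 3.18) and migratory dendritic cell-like cells 51 (2.20%, 1.64 to 2.88). A further 156 cells (6.73%, 5.75 to 7.83) formed an unnamed cluster with Ccr3, the eotaxin receptor. With a stricter cell filter its match, of 107 cells with 100 shared, met the naming rule for neutrophils, and the migratory dendritic cells lay in a cluster of 113 cells named conventional dendritic cell type 2-like. With variable genes of both libraries, 51 of the 57 T cell-like cells joined the Ccr3 cluster. The PBS library held 0 of 1344 cells in each of these clusters, and the Clopper-Pearson interval allows a share of up to 0.274%. Microglia-like cells, the resident macrophages of the retina, were in both libraries, with 105 PBS cells (7.81%, 6.43 to 9.38) and 412 MSC-sEV cells (17.8%, 16.2 to 19.4). The clusters behind them were 3 (65 and 224 cells) and 6 (40 and 188 cells). With a stricter cell filter the ratio of microglia-like shares was 1.36, against 2.28 here. By a marker score per cell, which needs no clusters, 71 PBS cells scored as leukocytes other than microglia beside 72 microglia, against 853 and 243 MSC-sEV cells. The 71 included 18 scored as monocytes or macrophages, 14 as plasmacytoid dendritic cells, 12 as plasma cells, 11 as B cells and 0 as T cells. The score gives each cell its best class, so single calls may be wrong.

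Transcripts over all barcodes showed the same split. Ccr2, the receptor that draws monocytes into tissue, had 1 UMI in the PBS library and 3354 in the MSC-sEV library. Ly6c2, a surface marker of classical monocytes, had 0 and 1571 UMIs, and Cd3e, a subunit of the T cell receptor complex, had 0 and 278. The gene of Ccr2 lies at chromosome 9, 124101950 to 124113557, and that of Ly6c2 at chromosome 15, 75108158 to 75111970 (mm10). The CD45 bead enrichment can set these shares. A cluster of 1 library only may also be that library and not a type.

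Named classes of retinal cells that passed the beads took a smaller share in the MSC-sEV library. All leukocyte clusters took 7.81% of PBS and 37.9% of MSC-sEV cells, which by itself lowers the other shares. A smaller share of all cells thus does not show a loss of that class. Rod-like cells were 35.1% (32.6 to 37.7) of PBS and 22.5% (20.8 to 24.3) of MSC-sEV cells. Müller glia-like cells, the main glia of the retina, were 9.67% (8.14 to 11.4) and 3.50% (2.79 to 4.33), and the ratio of these shares was 0.361. Without the 2% highest doublet scores it was 0.201, but the class then held 306 PBS and 106 MSC-sEV cells, against 130 and 81 here. Cone-like cells were 5.65% and 2.11%, bipolar cell-like cells 3.13% and 2.11%, and endothelial cell-like cells 1.56% and 0.432%. Other unnamed clusters held 37.1% and 31.5%. Of these, cluster 2 was higher in the MSC-sEV library (9.38% against 25.3%) and cluster 4 lower (18.2% against 1.34%). Both had the rod marker Sag among their top 10 genes, so the share of all retinal cells is not given by the named classes. Among leukocyte clusters alone, microglia-like cells were 105 of 105 in PBS and 412 of 877 (47.0%, 43.6 to 50.3) in MSC-sEV.

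**Figure D1:**
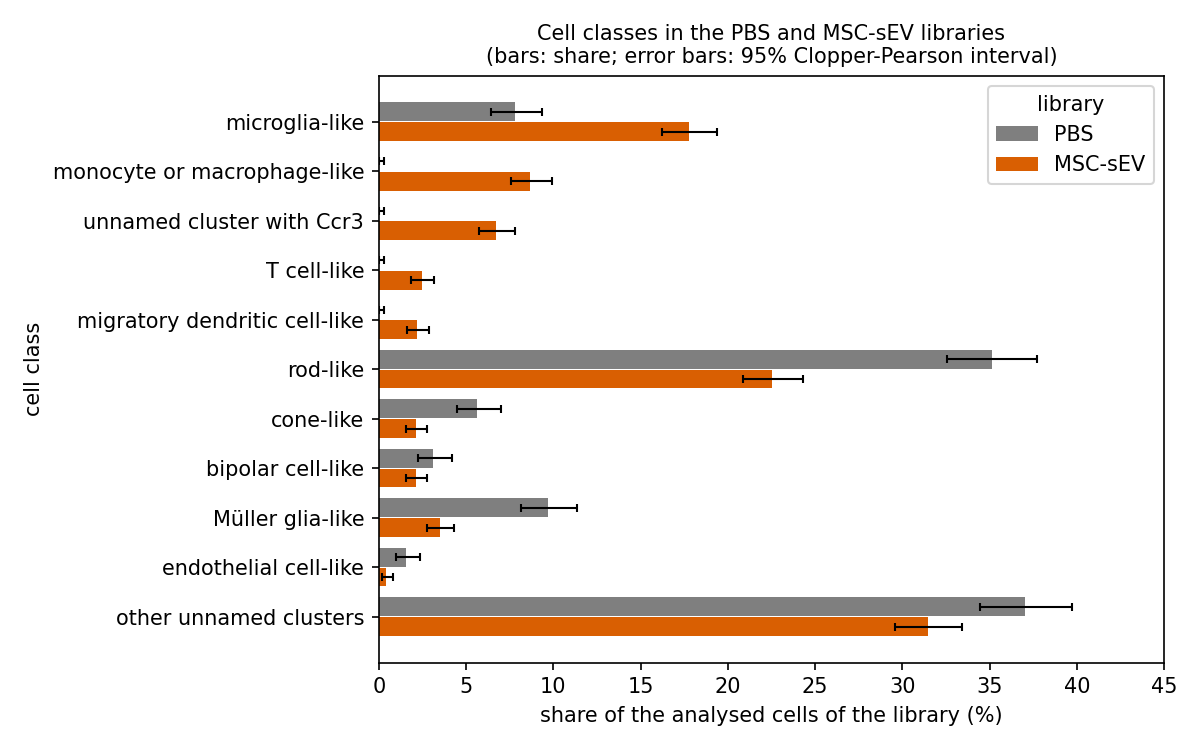
Share of analysed cells (%) in each cell class, for the PBS and MSC-sEV libraries, with 95% Clopper-Pearson intervals as error bars. Monocyte or macrophage-like cells were 0 in PBS and 8.68% in MSC-sEV.

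The monocyte or macrophage-like cells of the MSC-sEV library divided into 4 subclusters. Subcluster 3, with 51 of 201 cells (25.4%, 19.5 to 32.0), was classical monocyte-like, with Ly6c2 at 847 CPM, Ccr2 at 1671 CPM and Plac8 at 1942 CPM. It also held Arg1, the arginase of alternatively activated macrophages, at 5674 CPM and Ccl24, an eosinophil-attracting chemokine, at 6422 CPM. Its interferon response genes summed to 9826 CPM, against 2240 in subcluster 1 and 5244 in subcluster 2. Subcluster 2, with 58 cells (28.9%, 22.7 to 35.6), was conventional dendritic cell type 2-like, and held Cd209a, a lectin receptor, at 476 CPM and Cd74, the MHC class II invariant chain, at 19300 CPM.

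Subcluster 1, the largest with 74 cells (36.8%, 30.1 to 43.9), met the rule with 9 microglia markers and 5 of monocyte-derived macrophages. These markers were compared with the other subclusters only. Homeostatic microglia genes summed to 3795 CPM in subcluster 1, against 12013 CPM in microglia-like cells. The subcluster stayed unnamed because its top 10 genes held no microglia marker but held Apoe, which is on the Müller glia list. It held Apoe, a lipid carrier, Spp1 (osteopontin) at 3941 CPM and Gpnmb, a lysosomal glycoprotein, at 1499 CPM. Chil3, a chitinase-like protein of alternatively activated macrophages, reached 6718 CPM there, against 873 in subcluster 3 and 24.6 in subcluster 2. Arg1 reached 4566 CPM there and 162 CPM in subcluster 2. Subcluster 4 (18 cells, 8.96%) met the naming rule for rod-like cells, with rod markers such as Sag and Gnat1 at 1.73% of its UMIs. It also held MHC class II genes at 15624 CPM, against 201 CPM in rod-like cells, at median depths of 20088 and 2070 UMIs. Subclusters are described without a comparison between groups, and at resolution 2.0 they numbered 8.

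**Figure D2:**
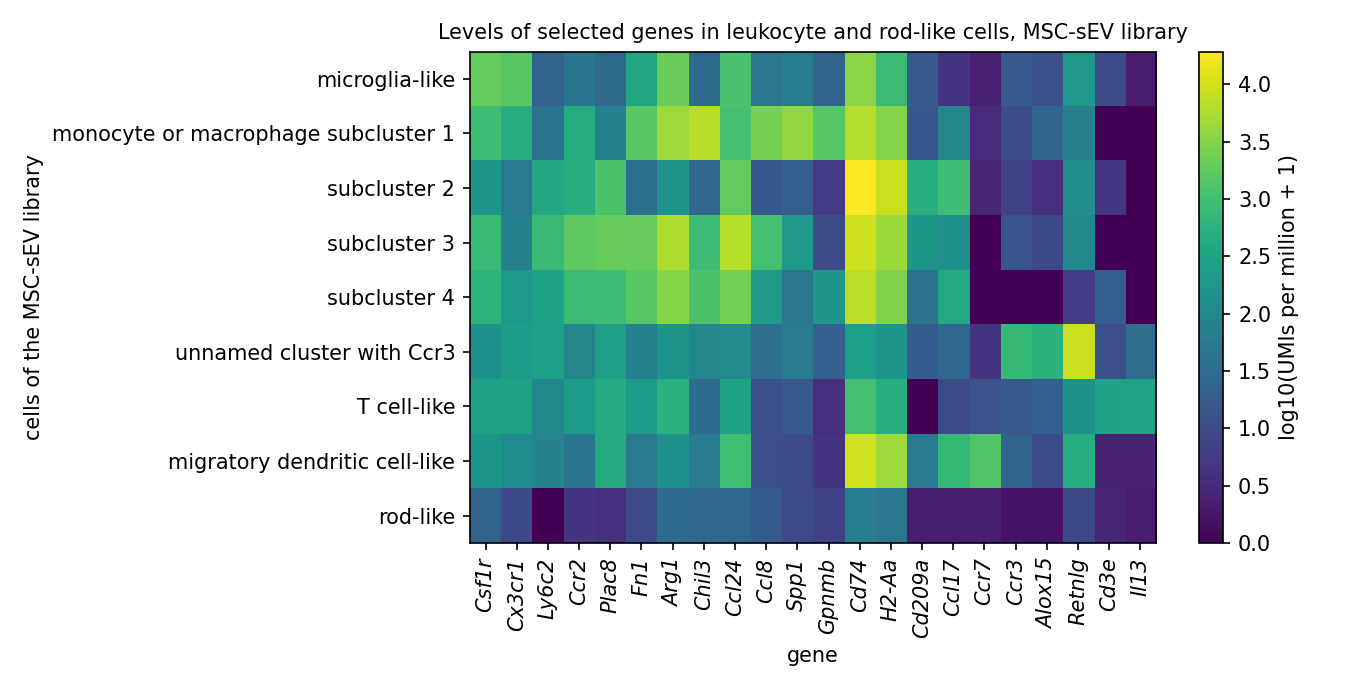
Levels of selected genes (columns) in leukocyte clusters, monocyte or macrophage subclusters and rod-like cells of the MSC-sEV library (rows), as log10(CPM + 1). Chil3 was 6718 CPM in subcluster 1 and 24.6 CPM in subcluster 2.

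The other leukocyte clusters of the MSC-sEV library carried genes of distinct immune functions. In T cell-like cells, Gata3, the regulator of type 2 helper T cells, had a UMI in 57.9% of cells (44.1 to 70.9), against 0.192% of rod-like cells, at median depths of 7434 and 2070 UMIs. The T cell coreceptors Cd4 and Cd8a were at 110 and 49.3 CPM. Il13, a type 2 cytokine, was at 312 CPM, from 9 of 57 cells, and Ifng, a type 1 cytokine, at 59.5 CPM, from 8 cells. Gzma and Gzmb, granzymes of cytotoxic cells, were at 743 and 184 CPM, Tbx21, the regulator of type 1 helper T cells, at 20.3 CPM, Foxp3, that of regulatory T cells, at 34.8 CPM and the IL-33 receptor Il1rl1 at 151 CPM. Rod-like cells held Il13 at 1.20 CPM, Gzma at 3.59 CPM and 0 UMIs of Ifng. Cd3e had a UMI in only 56.1% of the T cell-like cells. Ncr1, an NK cell marker, and Trdc, a gamma-delta T cell marker, had a UMI in 12.3% each. Gata3, Il13 and Il1rl1 are also markers of type 2 innate lymphoid cells, so the cluster may hold other lymphoid cells, which was not tested. Migratory dendritic cell-like cells held Ccr7, the receptor for lymph node homing, at 1310 CPM and Ccl22, a T cell-attracting chemokine, at 1313 CPM. In the unnamed cluster with Ccr3, the gene had a UMI in 62.2% of cells (54.1 to 69.8), against 0.192% of rod-like cells, at median depths of 1279 and 2070 UMIs. That cluster also held Retnlg, a resistin-like protein of granulocytes, at 8779 CPM, against 7.79 in rod-like cells.

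Microglia-like cells of the MSC-sEV library had higher levels of genes of antigen presentation, alternative activation and cell division. In the MHC class II list, 8 of 10 measured members were higher and 2 lower (median log2 ratio 2.54, percentile 100 among random lists), and the median was 1.61 in cluster 3 alone. Its invariant chain Cd74 was at 257 CPM in PBS and 3449 CPM in MSC-sEV (13.4-fold, 11.5 to 15.7), and H2-Aa, a chain of the presenting molecule, at 44.7 and 865 CPM (19.4-fold, 13.5 to 28.9). In the alternative activation list, 13 of 15 members were higher (median 2.63, percentile 100), with medians of 2.00 to 3.85 under the alternatives. Monocyte markers summed to 50.8 CPM in PBS and 548 CPM in MSC-sEV microglia-like cells. Arg1 had 0 UMIs in PBS and 9372 in MSC-sEV, which is at least 454-fold higher, and Fn1, a matrix protein, was 45.9-fold higher (19.6 to 142). Ccl24 had 2 and 5008 UMIs, a ratio of 364 (101 to 3007). Arg1 and Fn1 are also markers of monocyte-derived macrophages and classical monocytes. Whether such cells within the microglia-like class account for this list or the cell cycle list was not tested.

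All 20 measured cell cycle genes were higher in the MSC-sEV library (median 3.23, percentile 100). Top2a, the topoisomerase of dividing cells, was at least 43.0-fold higher (0 and 888 UMIs), and Mki67, a marker of proliferation, at least 34.0-fold higher (0 and 702 UMIs). Other named genes with 0 UMIs in PBS were the histone gene Hist1h1b (825 UMIs in MSC-sEV), the ubiquitin-conjugating Ube2c (431) of mitosis, the monocyte chemokine Ccl7 (457), the matrix genes Col6a3 (465) and Postn (424), and the antibody light chain Igkc (928, of which 882 in cluster 3). In cluster 6 alone, a setting chosen after seeing the data, the cell cycle median was 1.95, Top2a had 0 and 62 UMIs (at least 3.39-fold higher) and Mki67 0 and 155 (at least 8.47-fold). Hist1h1b had 0 and 13 UMIs there, so its log2 ratio of -0.49 rested on the floor of 3 counts, and with the stricter filter Ccl7 had 39 and 460 UMIs. C3, the central complement protein, was 54.2-fold higher (23.2 to 167).

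These levels were above those in rod-like cells, which carry RNA free in the droplets. Arg1 had a UMI in 72.8% of the 412 microglia-like cells (68.2 to 77.1) and 8.24% of rod-like cells of the MSC-sEV library, at median depths of 5752 and 2070 UMIs. Thinned to 1000 UMIs, with 25 PBS and 48 MSC-sEV cells left out, Arg1 was seen in 0 PBS and 51.1% of MSC-sEV microglia-like cells, Cd74 in 8.75% and 62.9%, and Mki67 in 0 and 7.42%. In thinned MSC-sEV rod-like cells these genes were seen in 2.17%, 6.99% and 0.723%. Igkc was an exception by share of cells, seen in 0.824% of thinned microglia-like and 1.45% of thinned rod-like cells. Most of its UMIs lay in few cells, so these shares do not settle whether it was free RNA. Unthinned, Cd74 was seen in 30.5% and 85.0%, and Mki67 in 0 and 18.9%. Arg1 lies at chromosome 10, 24915221 to 24927484, Ccl24 at chromosome 5, 135569937 to 135573049, and Cd74 at chromosome 18, 60803848 to 60812652 (mm10).

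Genes of interferon response and MHC class I were also higher in the MSC-sEV microglia-like cells. In the interferon list, 21 of 24 members were higher (median 1.23, percentile 100). Ifi27l2a, an interferon-induced gene, was 5.23-fold higher (4.55 to 6.03), and Rsad2, an antiviral enzyme, had 2 and 137 UMIs (ratio 9.96, 2.71 to 83.1). Cxcl10, an interferon-induced chemokine, had 1 and 194 UMIs (ratio 28.2, 5.004 to 1120). In the MHC class I list, 13 of 15 members were higher (median 0.60, percentile 99.9), with B2m, its light chain, 1.36-fold (1.30 to 1.42). Migration receptors were higher in 11 of 13 cases (median 1.22). Chemokines were higher in 10 of 15 cases and lower in 5 (median 1.11, -1.07 to 3.39), with Ccl2, a monocyte attractant, 3.28-fold higher (2.69 to 4.03). In cluster 3 alone the chemokine median was 0.037.

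Homeostatic microglia genes were lower in the MSC-sEV library in 15 of 17 cases (median -0.92, percentile 0). P2ry12, the purine receptor of resting microglia, was 3.64-fold lower (3.31 to 3.99), at 1074 CPM in PBS and 295 CPM in MSC-sEV. Gpr34, a lipid receptor, was also 3.64-fold lower (3.28 to 4.03). Cx3cr1, the fractalkine receptor, was at 2434 CPM in PBS and 1505 CPM in MSC-sEV. Several of these genes are also among the markers that name the class. With a stricter cell filter the median was 0.0074, and in microglia-like cluster 3 alone it was -0.068.

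Among further named genes, Hpgd, the enzyme that breaks down prostaglandins, was 16.8-fold lower in MSC-sEV microglia-like cells (13.3 to 21.3), at 391 and 23.3 CPM. Spp1 was 5.53-fold lower (4.65 to 6.57), Serpine2, a protease inhibitor, 5.29-fold (4.54 to 6.17) and the sulfotransferase Chst2 8.94-fold (6.09 to 13.2). The transcription factor Sox4 was 6.74-fold lower (4.47 to 10.2), Agmo, a lipid enzyme, 7.09-fold (4.26 to 11.8) and the protease Klk8 5.61-fold (3.83 to 8.19). Spp1 had a UMI in 11.4% of PBS and 20.9% of MSC-sEV cells, against 0.212% and 2.87% of rod-like cells. Median depths were 3148 and 5752 UMIs in microglia-like and 2572.5 and 2070 in rod-like cells, and thinned to 1000 UMIs the shares were 7.50% and 4.95%, against 0.249% and 1.69% of rod-like cells. The photoreceptor genes Unc119, Rcvrn and Rtbdn were 4.22-, 4.11- and 4.30-fold lower. Photoreceptor markers made up 1.34% of microglia-like UMIs in PBS and 0.407% in MSC-sEV. In cluster 3 alone the log2 ratios of Sox4 (3 and 17 UMIs), Klk8 (4 and 17) and Serpine2 were -0.75, -1.17 and -1.43, and Agmo had at most 3 UMIs in each library. With the stricter filter the log2 ratios of Hpgd, Spp1, Chst2 and Agmo were -3.16, -1.76, -2.24 and -1.75, and that of Unc119 was -4.16.

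Other lists in microglia-like cells lay closer to 0 or had members on both sides. Oxidative phosphorylation genes were higher in 21 of 24 cases (median 0.43), phagocytosis and lipid genes in 13 of 19 (0.44) and matrix remodelling genes in 9 of 12 (0.32). Pro-inflammatory genes were higher in 8 of 15 cases (0.34), with Il1b, a cytokine, 7.63-fold higher (5.74 to 10.4) and Nfkbia, an inhibitor of NF-kB, at 348 and 234 CPM. Complement genes were higher in 7 of 12 cases (0.29), and growth factors in 9 of 16 (0.16), with Igf1, a growth factor, 5.37-fold higher (3.82 to 7.79). Among genes at least 3 times above their level in rod-like cells, a setting chosen after seeing the data, growth factors were higher in 9 of 12 cases (median 0.87, percentile 99.3, against 65.7 among all genes). This filter kept all 9 higher members but only 3 of the 7 lower ones, so the rise of the median may come from the filter. Disease-associated microglia genes were higher in 11 of 23 cases (-0.12), glycolysis in 8 of 16 (-0.02), immediate-early genes in 12 of 22 (0.03) and colony-stimulating factors and receptors in 3 of 7 (-0.24). Lymphocyte activation genes were higher in 7 of 11 cases (0.44), naive lymphocyte genes in 4 of 6 (0.14) and sex-linked genes in 3 of 4 (0.20). With the stricter filter the median of oxidative phosphorylation was -0.40, of disease-associated genes 0.73, of phagocytosis 1.41 and of glycolysis -1.24. That of colony-stimulating factors and receptors was 0.71 there. In cluster 3 alone the medians of pro-inflammatory and immediate-early genes were 1.34 and 2.23.

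**Figure D3:**
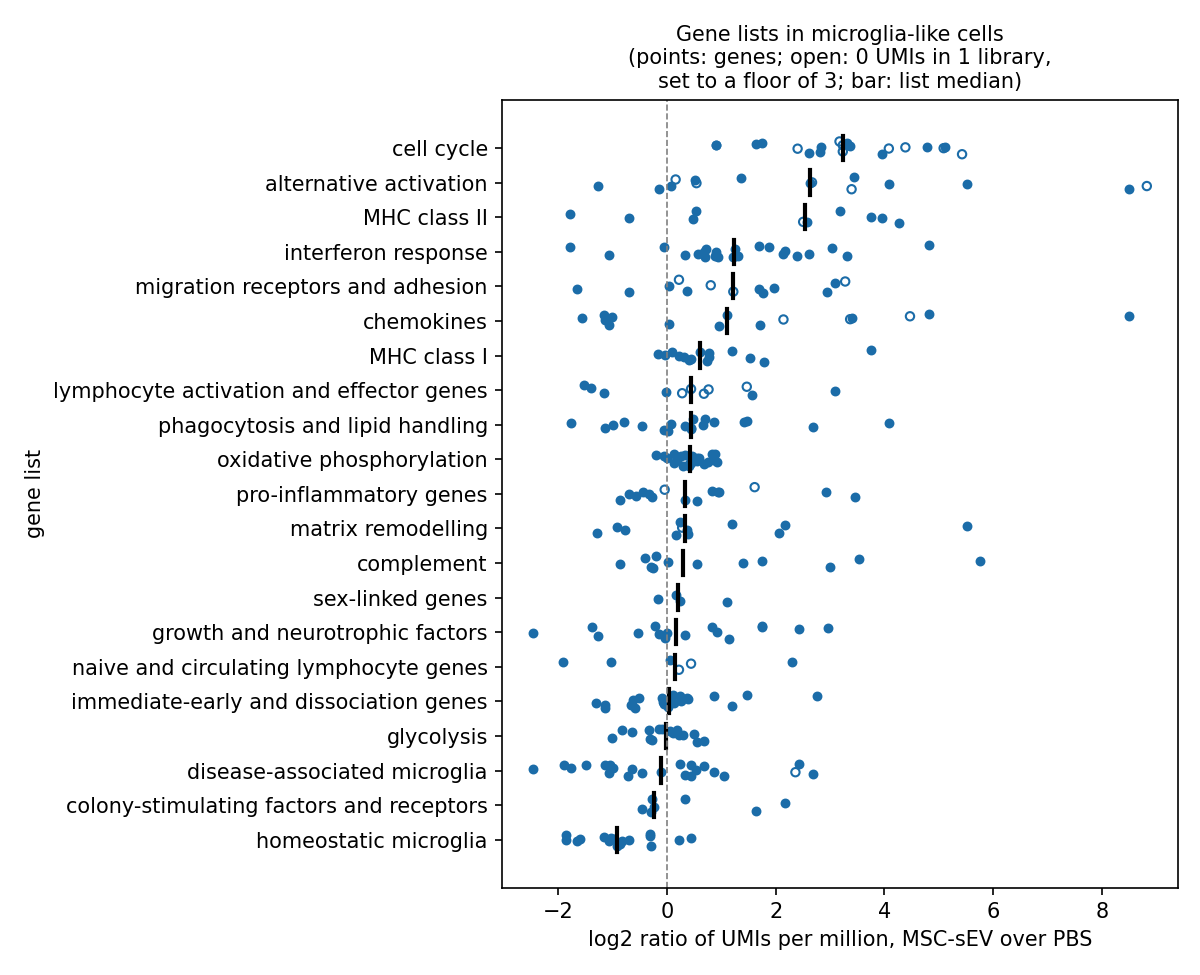
Log2 ratio of CPM (MSC-sEV over PBS) of each measured gene in microglia-like cells, by gene list, with the list median as a bar and open points for genes with 0 UMIs in 1 library. Cell cycle (3.23) had the highest and homeostatic microglia (-0.92) the lowest median.

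Rod-like cells of the MSC-sEV library had higher Fgf2, a growth factor that protects photoreceptors, at 48.6 CPM in PBS and 171 CPM in MSC-sEV (3.53-fold, 2.78 to 4.52). Rbp3, the retinoid-binding protein between photoreceptors and pigment epithelium, was 2.35-fold higher (2.26 to 2.44) and the matrix gene Impg2 2.58-fold (2.34 to 2.85). B2m was 3.42-fold higher (2.44 to 4.86) and H2-K1, an MHC class I chain, 3.37-fold (2.24 to 5.19). Monocyte markers, which rod-like cells should lack, summed to 20.8 CPM in PBS and 56.9 CPM in MSC-sEV rod-like cells. Ube3b, a ubiquitin ligase, was 3.20-fold (2.21 to 4.71) and Cpeb4, which binds mRNA tails, 2.81-fold higher (2.10 to 3.79). At resolution 0.5 the log2 ratio of B2m was 1.09, against 1.77 here. Fgf2 lies at chromosome 3, 37348346 to 37410108 (mm10).

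Among named genes with lower levels in MSC-sEV rod-like cells, Pdc, which binds transducin, was 1.79-fold lower (1.73 to 1.84), Pde6g, a subunit of the light-activated phosphodiesterase, 1.71-fold (1.67 to 1.74) and Rcvrn, a calcium sensor, 1.63-fold (1.59 to 1.68). Unc119 was 1.66-fold lower, Sept4 3.82-fold, Bc1 2.87-fold, Ilvbl 3.21-fold, Eif5a 1.94-fold, Rdm1 2.54-fold and Fn3k 2.45-fold. Photoreceptor markers made up 11.9% of rod-like UMIs in PBS and 10.3% in MSC-sEV. Glycolysis genes were lower in 12 of 14 cases (median -0.33, percentile 0.160), with Ldha, which makes lactate, at 1347 and 928 CPM. Oxidative phosphorylation genes were lower in 21 of 24 (median -0.17, percentile 7.24). Leukocyte genes were also higher here, with Cd74 at 1.60 and 65.9 CPM (41.2-fold, 13.7 to 203), H2-Aa 21.9-fold (8.22 to 82.3) and Lyz2, lysozyme, 6.41-fold (3.80 to 11.4). These levels lay below those of microglia-like cells of the library, which held Cd74 at 3449 CPM.

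Among named genes with higher levels in MSC-sEV Müller glia-like cells, Lcn2, an iron-siderophore carrier, was 279-fold higher (184 to 446), at 14.5 and 4054 CPM, and Serpina3n, a protease inhibitor, 22.8-fold (14.01 to 39.7). Timp1, an inhibitor of matrix proteases, was 17.8-fold higher (9.92 to 35.1), Ptgds, a prostaglandin synthase, 17.5-fold (14.7 to 20.9), the protease Prss56 12.1-fold (9.68 to 15.4) and Chil1 9.81-fold (7.53 to 12.96). C3 had 1 and 687 UMIs (ratio 873, 156 to 34547) and A2m, a protease inhibitor, 1 and 130 (ratio 165, 29.1 to 6577). Steap4 was at least 22.9-fold higher (0 and 54 UMIs), and Crispld2 was 21.1-fold higher (8.69 to 66.7). All 14 measured MHC class I genes were higher (median 1.34), against a median of 0.12 over all genes of the class. Monocyte markers summed to 47.5 CPM in PBS and 335 CPM in MSC-sEV cells of this class. Lcn2 lies at chromosome 2, 32384633 to 32388252 (mm10).

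Lcn2 had a UMI in 20.99% of these MSC-sEV cells and 8.46% of PBS cells, against 5.17% and 2.12% of rod-like cells. Median depths were 4139 and 6353 UMIs in Müller glia-like and 2070 and 2572.5 in rod-like cells. Thinned to 1000 UMIs, with 26 PBS and 21 MSC-sEV cells left out, Lcn2 was seen in 0.962% of PBS and 13.3% of MSC-sEV Müller glia-like cells. Oxidative phosphorylation genes were lower in 22 of 24 cases (median -0.24, percentile 11.8). Named genes with lower levels were Cartpt, a neuropeptide (188-fold, 112 to 344), Pcp4 (41.9-fold, 16.1 to 155), Sebox (17.3-fold), Eef1a2 (20.4-fold, 5.38 to 173) and the leukocyte genes Ccl3, Ccl5, Ccl12, Selplg and Fcgr1. Homeostatic microglia genes had a median of -1.41 in this class. After thinning, C3 was at least 16.2-fold higher (0 and 28 UMIs), and Ccl3 and Sebox had 4 and 0 UMIs each, so that their log2 ratios of 0.38 rested on the floor of 3 counts. With cells weighted equally, the log2 ratios of Serpina3n and Pcp4 were 2.31 and -3.08. UMIs of at least 3 microglia markers were found in 25 of 130 PBS cells (19.2%, 12.8 to 27.1) and 7 of 81 MSC-sEV cells (8.64%, 3.55 to 17.0).

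The cells with these markers had median depths of 28442 and 39379 UMIs, against 4114 and 2690 in the others, so leaving them out changed depth as well. Without them, a setting chosen after seeing the data, Lcn2 was 98.1-fold (59.3 to 176), Ptgds 16.3-fold and Serpina3n 14.7-fold higher (6.92 to 37.3). C3 had 1 and 243 UMIs (ratio 199.7, 35.5 to 7920) and A2m 1 and 89 (ratio 73.1, 12.8 to 2921). Prss56 was 7.84-fold (6.12 to 10.2), Chil1 2.70-fold (1.87 to 3.97) and Steap4 at least 6.57-fold higher (0 and 24 UMIs), and Cartpt 10.3-fold lower (34 and 4 UMIs). Sebox had 25 and 3 UMIs (10.1-fold lower, 3.09 to 52.5) and Eef1a2 14 and 2 (8.52-fold lower, 1.96 to 77.2). The MHC class I median was then 1.76, with 12 of 13 genes higher. The MHC class II median was 3.89, against -0.21 with those cells, and Cd74 was then at 69.2 CPM in MSC-sEV, against 65.9 in rod-like cells. Glul, the glutamine synthetase of Müller glia, was 2.11-fold lower (2.03 to 2.19). The median of oxidative phosphorylation genes was 0.059, that of homeostatic microglia genes 0.34, and the log2 ratio of Ccl5 0.39. The log2 ratio of Ccl12 was -1.13, against -3.40 with those cells. Ccl3 and Fcgr1 had at most 3 UMIs in each library, so no ratio was given for them.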

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

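All tests in this part were chosen only after the result was seen. Barcodes left out by the cell filter (329 PBS and 270 MSC-sEV) held 9 leukocyte markers more often in the MSC-sEV library, with intervals that did not overlap, and each of these genes was in at most 3 PBS barcodes. Arg1 was seen in 13.7% of these barcodes, Lgals3 in 9.26%, Fabp5 in 8.52%, Chil3 in 7.04%, Mmp12 in 5.19%, Ccl8 in 4.81%, Ccr2 in 2.96%, and Retnlg and Fn1 in 4.44% each. Rod-like cells of the library, which carry free RNA, held them in 8.24%, 5.36%, 10.3%, 7.47%, 1.92%, 4.98%, 1.15%, 2.49% and 2.87% of cells in the same order, and the intervals overlapped for all 9 genes. Median depths were 898.5 UMIs in these barcodes and 2070 in rod-like cells. Whether these barcodes hold leukocytes stays open.

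Leukocytes other than microglia-like cells were counted in 465 MSC-sEV cells and 0 PBS cells by clusters, of which 309 in named clusters and 156 in the unnamed cluster with Ccr3, and in 71 PBS cells by a marker score per cell. A general shortage of leukocytes in the PBS capture is argued against by their share of all leukocytes, whose upper 95% bound in PBS was 3.45% by clusters and 58.1% by the score, below the lower bounds of 49.7% (39.2% for named clusters) and 75.3% in MSC-sEV. Loss at the cell filter is argued against by 116 UMIs of 20 marker genes over all PBS barcodes, where the MSC-sEV level would give 8673. More blood in the MSC-sEV pool stays open. The haemoglobin ratio was 0.906 (0.898 to 0.915), but the CD45 beads select leukocytes, so haemoglobin need not follow the number of blood leukocytes. With 1 pool per group, the treatment cannot be told apart from the mice of the pool. Cells lost before barcodes were called, or held differently by the CD45 beads, were not tested, and an effect of MSC-sEV on entry of blood leukocytes may be 1 hypothesis among these.

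MHC class II genes were higher in microglia-like cells of the MSC-sEV library. Free RNA is argued against, since their summed level was 31.3 times that of rod-like cells (6275 and 201 CPM). Migratory dendritic cells are argued against as well, as their markers give a median share of 0.599% where the MHC class II excess needs 21.5%. Monocytes or macrophages within or joined to these cells stay open: their markers give a median share of 6.44% where 16.8% is needed, but single markers reach from 0.919% (Chil3) to 29.6% (Fn1). A response of microglia to MSC-sEV may remain as a hypothesis, and the mice of the pool were not separated from it.

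The unnamed cluster with Ccr3 held 156 cells, all from the MSC-sEV library. Shallow cells of the named classes are argued against, since the fixed markers of those classes account for 42.3% of the cluster (36.99 to 48.4), while shallow cells of the unnamed clusters were not tested. Neutrophils as its main cell stay open, since S100a8 or S100a9 was seen in only 15.4% of its cells (10.1 to 22.02), while its match of 107 cells under the stricter cell filter met the naming rule for neutrophils with 5 markers. Eosinophils, which carry CD45 and so may pass the beads, stay open as well: 4 of 11 genes of an eosinophil list met the naming rule (Ccr3, Cebpe in 47.4%, Alox15 in 43.6% and Siglecf in 20.5% of cells), against 2 of 14 neutrophil markers (Retnlg in 87.2% and Mmp9 in 34.0%). That list was written after the cluster was seen. No eosinophil list was fixed in advance, so the naming rule could not give that name under any cell filter. The granule genes Epx and Prg3 had 0 UMIs there, while Prg2 of the same list was seen in 16.03% of cells (12.67-fold above the other cells). The neutrophil markers Ly6g, Camp and Ngp had 0 UMIs there as well.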

How the results depend on the processing

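Alternatives without the 2% highest doublet scores, with 1 microglia-like cluster alone, with genes above rod-like levels, and without Müller glia-like cells holding microglia markers were chosen only after the results were seen. No paired analysis was possible because each group has 1 library, so the groups share fewer than 2 numbers. Subclustering on variable genes of both libraries was not run, since PBS had 0 monocyte or macrophage-like cells. Of 93 alternative values for shares and numbers of cells, 64 stayed within the counting interval. For named genes in microglia-like, rod-like and Müller glia-like cells these were 191 of 258, 201 of 220 and 195 of 231. Of gene list medians, 303 of 319, 167 of 168 and 217 of 224 stayed within the interval of the median. That interval shows the spread between genes and is wide for some lists, such as chemokines in microglia-like cells (-1.07 to 3.39). Staying within it thus does not show a stable median. No ratio was given where both libraries had at most 3 counts.

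With the stricter filter, the microglia-like share ratio was 1.36, that of all leukocytes 2.88, and the shares of monocyte or macrophage-like cells and of the Ccr3 cluster, there named neutrophil-like, 6.97% and 5.69%. Migratory dendritic cell-like cells had no value there and without the highest doublet scores, where they lay in a cluster of 113 conventional dendritic cell type 2-like cells, and T cell-like cells had none with variable genes of both libraries. In microglia-like cells the homeostatic median was then 0.0074, disease-associated 0.73, MHC class I 1.37, pro-inflammatory 1.19, phagocytosis 1.41, glycolysis -1.24, oxidative phosphorylation -0.40 and immediate-early 0.61. Of the 126 PBS cells called microglia-like under that filter, 47 had been in unnamed cluster 4 and 78 were microglia-like in the main setting, so the class itself differed. In cluster 3 alone the homeostatic median was -0.068, chemokines 0.037, pro-inflammatory 1.34, phagocytosis 0.97, oxidative phosphorylation 0.12 and immediate-early 2.23. Among genes above rod-like levels the growth factor median was 0.87 and that of alternative activation 2.00, and oxidative phosphorylation and sex-linked genes had no value. In cluster 6 alone cell cycle was 1.95 and Hist1h1b -0.49, from 0 and 13 UMIs against the floor of 3. With cells weighted equally, oxidative phosphorylation was 0.17 and immediate-early 0.40. The cause was not tested.

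Among leukocyte clusters only, which is another denominator, the microglia-like ratio was 0.470, monocyte or macrophage-like cells 22.9%, T cell-like 6.499%, migratory dendritic cell-like 5.82%, the Ccr3 cluster 17.8% and all leukocytes other than microglia 53.0%. By a marker score per cell these were 11.998% for monocyte or macrophage-like, 3.54% for migratory dendritic cell-like and 36.8% for all, with 71 PBS cells. Monocyte or macrophage-like cells were 5.91% at resolution 2.0 and 6.54% without the highest doublet scores, and the Ccr3 cluster 5.67% there and 9.11% with variable genes of both libraries, where it took in 51 T cell-like cells. The ratio of Müller glia-like shares was 0.201 without the highest doublet scores, where the class grew from 130 to 306 PBS cells and from 81 to 106 MSC-sEV cells. At resolution 2.0 there were 8 subclusters, with 13.9%, 21.9% and 18.4% for the best matches of subclusters 1, 2 and 3, and at 0.5 subcluster 4 matched 28.9%. In Müller glia-like cells, thinning gave log2 ratios of 0.38 for Ccl3 and 0.38 for Sebox, each from 4 and 0 UMIs against the floor of 3, and leaving out cells with microglia markers gave 0.39 for Ccl5 and a median of 0.059 for oxidative phosphorylation. The cause was not tested.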

Other observations

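The values in this part were chosen after they were seen and were not tested. Fgf2 was higher in the MSC-sEV library in rod-like and in Müller glia-like cells, where it was 5.02-fold higher (3.56 to 7.23). Edn2, a stress signal of injured photoreceptors, was 3.90-fold higher in rod-like cells (2.24 to 7.13). In Müller glia-like cells Osmr, the oncostatin M receptor, was 3.52-fold (2.22 to 5.75) and Stat3, a transcription factor of the same pathway, 3.43-fold higher (2.53 to 4.70). Osm, its ligand, was at 9.24 CPM in PBS and 71.9 CPM in MSC-sEV microglia-like cells (7.78-fold, 3.54 to 21.4).

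Over all barcodes, Il13, a type 2 cytokine, had 0 UMIs in PBS and 241 in MSC-sEV, and Il5 0 and 15. Ccl24, whose receptor is Ccr3, was at 6422 CPM in subcluster 3 and 1122 CPM in microglia-like cells. Retnla, a resistin-like gene of alternative activation, was at 4281 CPM in subcluster 1 and 2411 CPM in the cluster with Ccr3, against 16.2 in rod-like cells.

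Xist, expressed in female cells, had 22 UMIs in 8 PBS barcodes and 0 in the MSC-sEV library, and Ddx3y, a Y-linked gene, 478 and 1382 UMIs. Of the 928 UMIs of Igkc in MSC-sEV microglia-like cells, 882 came from 18 cells of cluster 3, and 6 migratory dendritic cell-like cells held 5709. Thinned, Igkc was seen in 0.824% of microglia-like and 1.45% of rod-like cells, while no cluster was named B cell-like. Csf3, the granulocyte growth factor, had 0 UMIs in both libraries.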
